A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

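Total RNA of 6 yeast samples, 3 of FY4 and 3 of the BAS1 deletion strain, was labelled with biotin and hybridised to Affymetrix arrays, per the labels. The deposited values are intensities on a linear scale, 1 per probe set and array. The submitters' processing notes name R 2.8.0, affy and RMA, a method of background correction, between-array normalization and probe summary. RMA gives no detection calls and compresses low values, so changes of dim genes can be understated. Probe signals near the top of the scale can be understated as well. The deposited arrays do not share 1 distribution: the log2 median over all probe sets was 7.81 to 7.89 in the wild-type arrays and 8.47 to 8.65 in the deletion arrays. Values normalized between arrays do not measure a global change in RNA amount.

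Here log2 of the deposited intensities was taken. Of 10928 probe sets, 5498 had 1 gene of the S. cerevisiae RefSeq table (assembly R64), 1746 had 1 gene outside that table, 1 had several genes, 3470 had none in the annotation used here, 166 were array controls and 47 were reporters. The annotation is old, and 12 probe sets had their symbols updated through gene identifiers. Each gene was represented by its probe set with the highest mean over all arrays, which gave 5449 genes. Of 47 genes with several probe sets, 2 (HXT9 and YLL066W-B) had probe sets that moved opposite ways at an unadjusted p under 0.05. The build behind the array annotation is not given in the sources used here, so no coordinates are printed, and the RefSeq table served for names, neighbours and chromosomes.

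The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term), with Benjamini-Hochberg adjustment over the 5449 genes and a threshold of 0.05. Standard errors are limma's moderated ones. The background level was the 95th percentile of the 1746 probe sets outside the S. cerevisiae table, 6.09 in log2 over all arrays, or the array's own 95th percentile where that was higher. Where a group's mean lay under the mean of its arrays' levels, the fold is a bound against, in each array, the higher of that level and the measured value. This rule for bounds was set after the data were seen. Gene lists were tested with camera (preset correlation 0.01, and estimated), with adjustment over the 28 lists fixed beforehand and, separately, over 12 lists added after the data were seen, and with fry.

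On simulated values for this comparison (5449 genes, 200 changed), limma recovered 62 of 100 genes changed by 0.5 log2 and 88 of 100 changed by 1 log2. Among its 156 calls, 6 were false. The simulated genes varied independently, whole arrays were not shifted, and far fewer genes changed than were called in the data. These rates need not carry over.

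The test between strains, the gene list tests, the 28 lists and the rule for named genes were fixed before the data were examined. The 12 added lists, and most tests of explanations, were chosen afterwards. The rule takes BAS1, PHO2, GCN4, the nearest tested genes on either side of BAS1, the 10 largest rises and 10 largest falls among called genes without overlap between groups, and up to 4 members per list, with any member of the purine, one-carbon and histidine lists allowed. Alternatives were the replicate number as a block, other normalizations, filters and probe set rules, a variance trend, array weights, a stricter threshold of 0.01 and leaving out each replicate. Spike level as a block and the arrays of each spike level alone were added after seeing the data. No 2 arrays held identical values, and correlations across genes ran from 0.988 to 0.995 within strains and from 0.909 to 0.929 between them.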

Results

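Messenger RNA levels were measured on Affymetrix arrays in 6 samples of budding yeast: 3 of the reference strain FY4 and 3 of a strain lacking BAS1, the gene of a Myb-family transcription factor known for activating purine and histidine synthesis genes. Per the labels, the cells grew exponentially in minimal medium with glucose. The values are intensities, and levels are given as log2 of them with the SD over 3 arrays. The median over the 5449 tested genes lay between 10.94 and 10.997 in the wild-type arrays and between 11.10 and 11.14 in the deletion arrays. The number of arrays limits the precision. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples.

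The deleted gene was read first, as a check of the labels. BAS1 (YKR099W) stood at 11.09 ± 0.12 (SD, n = 3) in wild type and at 4.83 ± 0.06 (SD, n = 3) in the deletion strain, a log2 difference of -6.27 with a limma standard error of 0.07 and an adjusted p of 2.7e-07. All 3 deletion values lay under background. The background level was the 95th percentile of probe sets for genes outside the S. cerevisiae table, 6.09 over all arrays, or the array's own percentile where higher. That percentile ran from 6.22 to 6.60 in the wild-type arrays and from 5.73 to 6.12 in the deletion arrays. BAS1 was thus at least 31.9-fold lower. An exact two-sided permutation test of the 6 values gave p = 0.1, the smallest that 3 against 3 arrays allow.

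The comparison asked which genes differ between the deletion strain and FY4. The largest fall after BAS1 was in ADE17, which encodes the enzyme of the closing steps of IMP synthesis and fell 11.4-fold (log2 difference -3.51, SE 0.05). GCV1, which encodes a subunit of the glycine cleavage complex, fell 6.88-fold (log2 difference -2.78, SE 0.08). The largest measured rise was in NCA3, 63.6-fold higher (log2 difference 5.99, SE 0.10). ARO9, an aromatic aminotransferase, was at background in wild type and rose at least 39.7-fold. ARO10, a phenylpyruvate decarboxylase, rose 27.3-fold, with 2 of its 3 wild-type arrays above background. Of the amino acid permease genes, BAP2 was at background in wild type and rose at least 31.6-fold, and AGP1 rose 21.0-fold. With n = 3 per strain, limma called 3241 of 5449 genes at an adjusted p under 0.05, of which 2160 were higher and 1081 lower in the deletion strain. At least 2-fold changes were found in 516 genes, 454 higher and 62 lower.

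The median log2 difference of all tested genes was 0.11 rather than 0, and the split by direction moved with the scaling. Centring each array on its median gave 1481 higher and 1803 lower genes, so the share of higher calls went from 66.6% to 45.1%, and quantile normalization over the tested genes gave 41.2%. Cytosolic rRNA control probe sets, which can reflect how the RNA was prepared or a difference between the strains, moved with strain as well. All 16 such probe sets for S. cerevisiae 18S and 25S rRNA had lower means in the deletion arrays, 14 of them past the threshold, with a median log2 difference of -3.09. The 5.8S probe set, not among the 16, differed by -0.43 (limma adjusted p = 0.092). Every gene group below was measured on those same arrays. Poly-A spike controls split the arrays another way, into 3 low arrays (2 wild type and 1 deletion) and 3 high arrays (1 wild type and 2 deletion). Between spike levels, with strain in the fit, limma called 0 genes, and 939 lay at an unadjusted p under 0.05, where chance gives about 272. Within the low-spike arrays limma called 1593 genes and within the high-spike arrays 2420. Each of these fits, and each value within a spike level below, sets 2 arrays against a single one, which is assumed to vary like the others. All 3241 genes called over the 6 arrays had the same direction within both sets, though this is not independent, since they were called on these arrays.

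Among the other large rises, YRO2 was 27.1-fold, CDA1, a chitin deacetylase gene of spore wall formation, 19.0-fold and SPG4 19.2-fold higher, with 1 of its 3 wild-type arrays above background. SRL4 and MF(ALPHA)1, a gene for the mating pheromone alpha-factor, lay at background in wild type and were higher by at least 3.44 and at least 3.47 log2. Among the other large falls, YMR230W-A fell 9.53-fold, SFG1 3.76-fold and EEB1, an ethyl ester synthase gene, 3.75-fold. YBL044W and YDR034C-A were at background in the deletion strain and at least 1.65-fold and at least 2.85-fold lower, with 2 of 3 wild-type arrays above background for YBL044W. YOR008C-A was at background in both strains, so no fold is given. PHO2, whose product acts with Bas1, differed by 0.20 (SE 0.05, adjusted p = 0.012), a difference of -0.0069 after quantile normalization. GCN4, the activator of amino acid synthesis genes, differed by 0.17 (SE 0.09, adjusted p = 0.145).

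All 9 measured genes of purine synthesis fell, also when adjusted over the list alone, with a median log2 difference of -1.33. After ADE17, ADE4, which encodes the enzyme of the committed step, fell 3.38-fold, ADE1 3.36-fold and ADE8 2.92-fold. The smallest fall was in ADE16, the paralog of ADE17, at 1.22-fold (log2 difference -0.28, SE 0.04). The camera test against all other genes gave an adjusted p of 7.5e-09 over 28 lists, and an adjusted p = 0.273 with an estimated correlation. The list median was -1.32 within the low-spike arrays and -1.38 within the high-spike arrays.

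**Figure D1:**
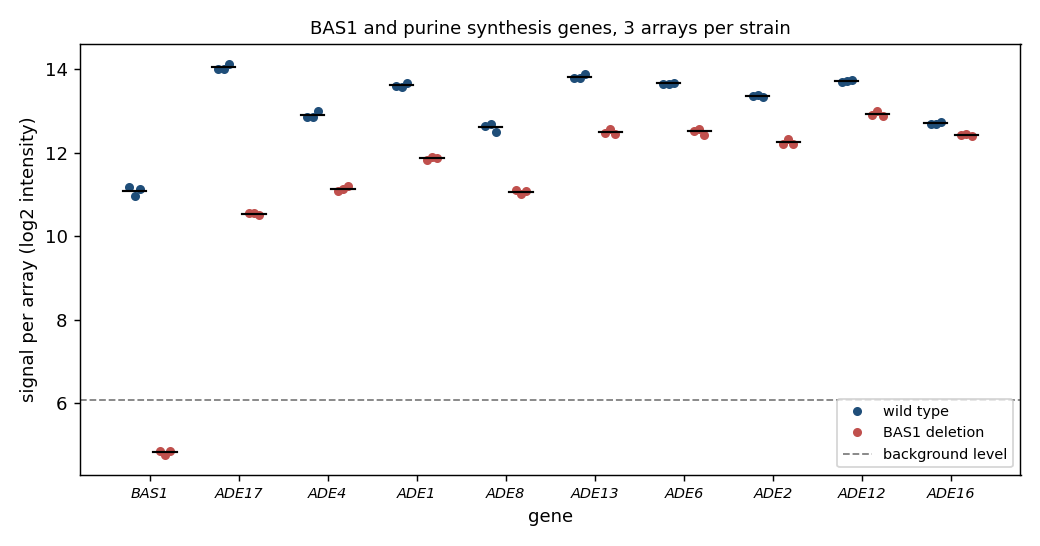
Signal per array, in log2 intensity, of BAS1 and the 9 measured purine synthesis genes. Points are arrays, 3 per strain, black bars are group means and the dashed line is the background level over all arrays, 6.09. BAS1 lies under that line in the deletion strain, and ADE17 fell most among the purine genes.

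Of 15 genes of one-carbon and glycine cleavage metabolism, 9 fell and 2 rose (11 and 1 after array centring), and adjusted over the list alone 9 fell and 3 rose. SHM2, the cytosolic serine hydroxymethyltransferase gene, fell 3.90-fold, GCV3 2.64-fold and MTD1 2.55-fold. LPD1, whose product is shared with other mitochondrial dehydrogenases, rose 1.51-fold. The list's median was -0.37, with a camera adjusted p of 0.0013, and an adjusted p = 0.42 with an estimated correlation. Its median was -0.38 within the low-spike arrays and -0.39 within the high-spike arrays.

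All 7 serine and glycine genes changed, 5 falling and 2 rising, with the same counts when adjusted over the list alone. SER3 and SER2 of serine synthesis fell 3.32-fold and 2.50-fold, while AGX1, the alanine:glyoxylate aminotransferase gene of glycine synthesis, rose 10.6-fold and GLY1, the threonine aldolase gene, rose 1.80-fold. The list's median was -0.32, its mean was 0.014, and its camera adjusted p was 0.0747. Its median was -0.38 within the low-spike arrays and -0.33 within the high-spike arrays. Of the 7 histidine synthesis genes, 5 fell and 2 rose, also when adjusted over the list alone, and 5 and 1 after array centring. HIS4 fell 2.32-fold and HIS1 1.61-fold, and HIS3 rose 1.32-fold. Their median was -0.28 with a camera adjusted p of 0.0524, and it was -0.29 within the low-spike arrays and -0.23 within the high-spike arrays. With an estimated correlation the camera adjusted p was 0.42 for serine and glycine and 0.559 for histidine synthesis. Limma's fry tests whether a list's genes lean in the same direction on balance, without comparing them with other genes. It gave an adjusted p of 1.1e-05 for purine synthesis and 6.3e-04 for one-carbon metabolism. For each of the serine and glycine and the histidine list it was 0.0064. Passing fry does not set these lists apart. Lists that camera did not call passed fry too, such as purine salvage (adjusted p = 1.8e-04), hexose transport (adjusted p = 0.0027) and strain marker genes (adjusted p = 4.2e-04). The marker list is not separate, since it holds ADE2 and HIS3, which are also in the purine and histidine lists. Of the lists fixed beforehand, fry left uncalled only lysine (adjusted p = 0.152) and branched-chain synthesis (0.731), ribosome biogenesis (0.198), a-cell genes (0.355) and haploid markers (0.471).

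Of 24 stress response genes, 22 rose and none fell. YGP1 rose 16.1-fold, HSP12 11.5-fold and DDR2 10.3-fold. Of 38 genes of the TCA cycle and the respiratory chain, 37 rose and 1 fell, among them SDH2, a succinate dehydrogenase subunit, 3.71-fold higher, and CYC1, cytochrome c, 3.64-fold higher. The list medians were 0.98 and 0.95, with camera adjusted p of 7.5e-06 and 1.8e-08. With an estimated correlation the adjusted p was 0.447 and 0.42.

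Thiamine genes rose in 13 of 14, with THI13 at 11.7-fold (on a probe set that matches several transcripts) and THI4 at 3.82-fold, and iron regulon genes in 12 of 14, with FIT2 at 16.0-fold and SIT1 at 6.78-fold. Camera gave an adjusted p of 6.1e-05 and 7.9e-04, and with an estimated correlation an adjusted p of 0.273 and 0.323. Of 23 sulfur amino acid genes, 17 rose and 1 fell, or 10 and 3 after array centring (camera adjusted p = 0.0343), led by SAM3 at 2.75-fold, but the adjusted p was 0.0976 after array centring, 0.0502 without wild-type replicate 1 and 0.6 with an estimated correlation. In the phosphate regulon 10 of 15 rose and none fell (7 and 3 after array centring), with PHM8 13.4-fold (2 of its 3 wild-type arrays above background) and the transporter gene PHO84 13.2-fold higher. The camera adjusted p was 0.0524, then 0.0488 without deletion replicate 3, 4.2e-04 against all probe sets and 0.42 with an estimated correlation. Here and below, all probe sets means the array's 10928, with controls, 1746 outside the S. cerevisiae table and 3470 without a gene. A call gained or lost there can come from that change of comparison set. Of 18 nitrogen catabolite genes, 10 fell and 6 rose (camera adjusted p = 0.0418), with DAL5 3.17-fold lower and DUR3 2.63-fold higher. Their adjusted p was 0.122 after quantile normalization, 0.135 after array centring, 0.0893 after cyclic loess, 0.0671 with spike level as a block, 0.0564 without deletion replicate 2, 0.247 against all probe sets and 0.42 with an estimated correlation.

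Among 128 cytosolic ribosomal protein genes 69 fell and none rose (105 and 0 after array centring), and RPS14B fell most, 2.28-fold. Their median was -0.21 (-0.37 after array centring), with a camera adjusted p of 5.4e-16 and an adjusted p = 0.323 with an estimated correlation. Of 40 ribosome biogenesis genes 12 fell and 2 rose (19 and 0 after array centring), with a median of -0.0955 (-0.25 after array centring). Their camera adjusted p was 0.0030, and the adjusted p was 0.137 against all probe sets and 0.805 with an estimated correlation.

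All 4 genes specific to alpha cells passed the threshold as higher (3 after array centring), with STE3, the receptor for a-factor, at 4.34-fold. MF(ALPHA)2 turned lower, at -0.56, after quantile normalization. The list's camera adjusted p was 0.0343, then 0.164 after quantile normalization, 0.0569 after cyclic loess, 0.0518 without wild-type replicate 2 and 0.42 with an estimated correlation. Of 7 genes specific to a cells, 1 rose and 1 fell (1 and 2 after array centring), and BAR1 was 1.53-fold lower. Of 10 sporulation genes 4 rose and 3 fell, with SPR3 8.07-fold higher (2 of its 3 wild-type arrays above background) and SPS4 3.18-fold lower (the list median, 0.24, was -0.38 after quantile normalization and -0.064 after cyclic loess), and of 8 haploid markers 3 rose and 3 fell. Camera gave an adjusted p of 0.474, 0.875 and 0.511 for these 3 lists.

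**Figure D2:**
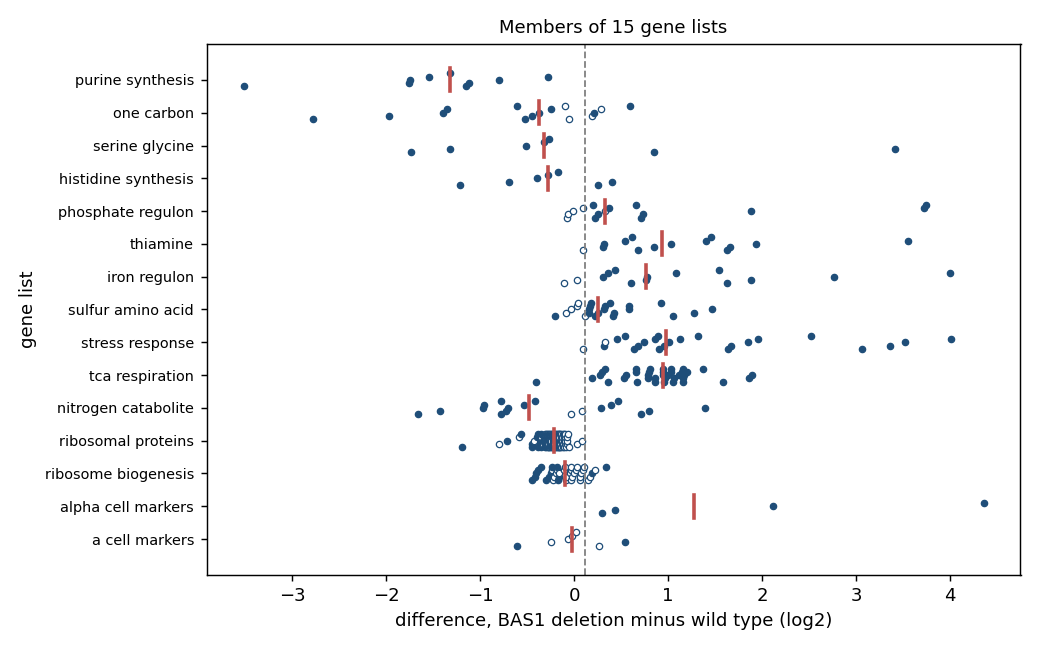
Log2 difference, deletion minus wild type, of each measured member of several gene lists. Filled points passed an adjusted p under 0.05, open points did not, red bars are list medians and the dashed line is the median of all tested genes, 0.11. Purine synthesis lies at a median of -1.33, and the stress list at 0.98.

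The remaining lists did not pass the camera test on the values as deposited. Glycolysis passed it after cyclic loess (adjusted p = 0.0212), and glycolysis and aromatic synthesis did against all probe sets (adjusted p = 0.0185 and 0.0108). With an estimated correlation the adjusted p was 0.859 for both. Purine salvage held 6 rises and 3 falls in 15 genes, with FCY21, a purine-cytosine permease homolog, 8.63-fold higher and HPT1, the hypoxanthine-guanine phosphoribosyltransferase gene, 3.43-fold lower. IMD2, an IMP dehydrogenase gene, rose 2.88-fold on a probe set that matches several transcripts, and GMP synthesis held 1 rise and 1 fall in 5 genes. PRPP synthesis had 1 rise in 5 genes, arginine synthesis 6 rises and 2 falls in 8, lysine synthesis 2 rises and 1 fall in 8, and branched-chain synthesis 3 rises and 4 falls in 11. Aromatic synthesis had 9 rises and 1 fall in 13 genes, pyrimidine synthesis 4 of each in 9, and glycolysis 6 rises in 15. Hexose transport had 5 rises and 2 falls in 12. Of its genes, 3 rose at least 2-fold, by up to 2.76 log2, and HXT7, on a probe set that matches several transcripts, was 2.01-fold lower. Strain marker genes had 1 rise and 3 falls in 6. Their camera adjusted p lay between 0.0747 for the marker genes and 0.94 for purine salvage. Array centring turned the balance of some of these counts, to 1 rise and 3 falls for PRPP, 4 and 5 for purine salvage, 1 and 4 for lysine and 1 and 2 for GMP synthesis. It gave 4 and 2 for aromatic synthesis, 1 and 5 for branched-chain synthesis, 2 and 0 for glycolysis, and 2 and 4 for the haploid markers. Median, mean and camera direction differed in sign for the GMP, PRPP, salvage, lysine, branched-chain and pyrimidine lists, and for the haploid markers and the serine and glycine list. Adjusted over the list alone, the counts differed from those over all genes in few lists. There, 67 ribosomal protein genes fell, 8 ribosome biogenesis genes fell and 1 rose, 5 branched-chain genes fell, no lysine gene fell and 5 glycolysis genes rose.

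The genes next to BAS1 were all higher in the deletion strain. PCK1 rose 3.70-fold, UBP11 1.88-fold, SKG1 1.22-fold and SIR1 1.56-fold. The SKG1 call (adjusted p = 0.0223) ended after array centring, quantile normalization or cyclic loess. Chromosome medians ran from 0.068 to 0.218 over 16 chromosomes, and camera called 0 of them, with 0 at an unadjusted p under 0.05.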

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

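A reporter probe set, outside the comparisons of named genes, gave a signal in the deletion arrays that the wild-type arrays lacked. It read 4.27 ± 0.25 (SD, n = 3) in wild type, at background, and 14.39 ± 0.03 (SD, n = 3) in the deletion strain, a log2 difference of at least 7.94. Another reporter probe set shares the first part of its name, but need not read the same sequence. It was at background in both strains, 5.12 ± 0.22 (SD, n = 3) in wild type and 5.04 ± 0.10 (SD, n = 3) in the deletion strain, with a limma adjusted p of 0.674. The annotation used here names no gene for either. Whether the signal of the first probe set comes from a marker put in place of BAS1 was not settled, so it is not read as the level of a yeast gene.

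Among 3470 probe sets with no gene in the annotation used here, 22 were at least 2-fold higher in the deletion arrays and above background in each of them. Of 83 that were at least 2-fold lower, 24 were above background in each wild-type array. The annotation used here does not give the species these probe sets were made for, so they are not read as S. cerevisiae transcripts.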

How the results depend on the processing

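The alternatives built on spike level were chosen after seeing the data. BAS1 kept its direction and call under every alternative run, with log2 differences from -6.57 to -6.21. Counts moved with scaling: quantile normalization called 1356 raised and 1935 lowered genes, and array centring 1803 lowered. The stricter threshold left 679 lowered genes, by construction. Low-spike arrays alone called 1593 genes, 1102 raised and 491 lowered, and high-spike arrays alone 614 lowered, each from 2 arrays against 1. Spike level as a block called 3417 genes.

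With an estimated correlation the purine (median -1.33, adjusted p = 0.273) and one-carbon (median -0.37, adjusted p = 0.42) lists lost their call, and 0 of the other lists passed, against 9. In all 28 lists, camera then gave 4 at an unadjusted p under 0.05. With 1 array left out, the histidine medians ran from -0.32 to -0.24, and the list gained a call only without deletion replicate 1 (-0.29, adjusted p = 0.0462) or 2 (-0.32, adjusted p = 0.0353). Against all probe sets the lowest camera adjusted p of a chromosome was 6.1e-04, and the largest deviation of a chromosome median was 0.103. These need not belong to the same chromosome. There yeast genes are also set against probe sets that are not yeast genes, so this is not read as a chromosome shift. The nitrogen catabolite list lost its call in the low-spike arrays alone (adjusted p = 0.0701), and the sulfur (adjusted p = 0.0992) and alpha-cell (adjusted p = 0.0882) lists in the high-spike arrays alone. The cause of these changes was not tested.

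The replicate numbers share only a number: deviations of same-numbered arrays correlated at 0.44, -0.51 and -0.44. Across numbers, wild-type array 3 correlated with deletion array 2 at 0.75, and wild-type array 2 with deletion array 3 at 0.46. This shared pattern does not follow the spike levels alone and was not fitted, and its cause was not tested. The replicate block called 3140 genes and brought histidine synthesis, at -0.283, past the threshold (adjusted p = 0.0476).

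Quantile normalization turned the sign of MF(ALPHA)2 (-0.56, still past the threshold) and PHO2 (-0.0069, no longer past it), and leaving out shared probe sets turned that of the seripauperin list (-0.24, adjusted p = 0.828, 3 genes left). Of all 148 named genes, 34 lost their call with no change of direction, and 10 gained one, under at least 1 alternative. Most of the 34 lost their call in the low-spike arrays alone, a fit of 2 arrays against 1. Where both spike levels were kept, no alternative lost more than 11 calls, the number lost after array centring. Genes near the background level of 6.09 are limited by signal.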

Other observations

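The gene lists in this part were chosen after the data were seen, and so were the tests of RNA degradation, array scaling, spike batch, rRNA content, Sum1/Hst1, glucose and slow growth. Camera p-values here are adjusted over these 12 lists alone. Intervals of list medians in this part come from resampling a list's genes. They leave out the spread between arrays and treat genes that move together as separate. All 9 amino acid and peptide permease genes induced by external amino acids rose (median 1.91, camera adjusted p = 2.0e-04, and adjusted p = 0.417 with an estimated correlation). Beside BAP2 and AGP1, the tryptophan permease gene TAT2 rose 7.09-fold, DIP5 3.93-fold and MUP1 3.77-fold. Of 34 autophagy genes 23 rose and 1 fell (median 0.59, camera adjusted p = 7.4e-04), and of 12 genes of fatty acid beta-oxidation 9 rose and 2 fell, with POT1, the thiolase gene, at background in wild type and at least 3.87-fold higher (camera adjusted p = 0.0331). With an estimated correlation the adjusted p was 0.458 and 0.581. The beta-oxidation call also ended after quantile normalization (adjusted p = 0.0527) and cyclic loess (adjusted p = 0.0544). The autophagy list kept its call under both, with smaller medians of 0.27 and 0.35. Of 6 genes of NAD synthesis 4 rose, with BNA2 9.03-fold higher, and the camera adjusted p was 0.105, or 0.0054 against all probe sets and 0.458 with an estimated correlation.

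Of 13 probe sets for seripauperin genes 11 rose and 1 fell (camera adjusted p = 0.0068, and 0.458 with an estimated correlation), but 10 of them match several transcripts, so these may not be separate genes rising. Without those, 3 genes were left, PAU5 at 0.71, PAU17 at -0.32 (not called) and PAU23 at -0.24, and the call ended (adjusted p = 0.828). Of 7 core histone genes 3 fell, or 5 after array centring (camera adjusted p = 0.0149, and 0.581 with an estimated correlation). Their call ended after quantile normalization (adjusted p = 0.0676), cyclic loess (adjusted p = 0.0544) and in the high-spike arrays alone (adjusted p = 0.0599). Mitochondrial ribosomal proteins (13 rises and 3 falls in 66), proteasome (10 and 5 in 34) and ergosterol genes (11 and 2 in 20) had a camera adjusted p of 0.671, 0.973 and 0.588. Adjusted over the list alone the counts were 5 and 2, 9 and 2, and 12 and 2, and for the autophagy genes 25 and 2. Array centring turned the balance of the first 3, to 4 rises and 16 falls, 5 and 12, and 3 and 6. Against all probe sets the ergosterol list passed (adjusted p = 0.037, and 0.991 with an estimated correlation).

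The median over the 18S and 25S rRNA probe sets, though not every probe set, was lower in each deletion array, at -3.45 to -2.55 log2 relative to the wild-type mean. Array scaling is argued against by the hybridisation spikes, whose median difference was -0.017 (range -0.19 to 0.20). A preparation batch seen in the poly-A spikes is argued against by a median difference of 0.217 between spike levels within strains. RNA degradation is not decided by 3' minus 5' differences in 8 yeast control genes, which read mRNA and not rRNA. Tag controls, which are not yeast genes, were left out after their values were seen. The median strain difference was 0.122 (range -0.22 to 0.37). The 3' minus 5' difference was larger in the deletion strain for SRB4 (by 0.37), URA3 (0.22), EAF5 (0.21), WBP1 (0.19), SPT15 (0.051) and ACT1 (0.039). It was smaller for RIP1 (-0.073) and TDH1 (-0.22). Evenly lower rRNA in the cells is argued against by falls that spanned 3.53 log2 over 11 probe sets. How rRNA was primed or carried along in labelling, if it followed strain, may account for the pattern and stays open, as do RNA degradation and a biological difference between the strains.

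Alpha-specific MF(ALPHA)1 and STE3 were higher in the deletion strain. Lower SIR1, a silencing gene beside BAS1, is argued against, since SIR1 was higher by 0.638 (limma's 95% interval 0.49 to 0.79). MATalpha cells among the deletion cells may contribute. The 15 genes that respond to alpha-factor had a median of 0.17, with an interval of -0.079 to 1.27 that does not decide. That median was -0.19 after quantile normalization. Of the 15, 6 rose and 4 fell. PRM2 was 5.32-fold and FIG1 at least 4.58-fold higher, from wild-type means of 6.98 and 6.32. PRM3 was 1.88-fold and SST2 1.58-fold lower, from wild-type means of 10.6 and 11.6. Loss of Sum1/Hst1 repression is likewise undecided, as 17 middle sporulation genes had a median of 1.90 (interval -0.14 to 2.96), 11 rising and 4 falling, with a camera adjusted p of 0.176, or 0.0194 after array centring, 0.0018 against all probe sets and 0.714 with an estimated correlation. The strain difference itself stays open, untested.

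Stress and respiratory genes were higher in the deletion strain. Normalization between arrays is argued against as the whole cause, since the stress median was 0.839 after quantile normalization over the tested genes. Its interval, over genes only, was 0.56 to 1.502. A common slow-growth programme may contribute and stays open: ribosome biogenesis genes had a median of -0.21 relative to all genes (interval -0.30 to -0.14), and ribosomal protein genes one of -0.33, with 69 of 128 falling, or 105 after array centring. Glucose depletion before harvest may contribute and is not decided. The 12 glucose-repressed genes had a median of 0.405 (interval -0.20 to 1.21), and that median was -0.0069 after quantile normalization. The list was mixed, with 6 rising and 2 falling. PCK1, also a neighbour of BAS1, stood at 1.89, MDH2 at 1.84 and HXT7, on a shared probe set, at -1.01. An effect of the deletion itself was not tested and stays open.

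The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. In each of the results that follow, 1 of the 10 splits, the real one, gave a result as large. It gave 3241 changed, 2160 raised, 1081 lowered and 516 at least 2-fold changed genes, and 9 purine, 11 one-carbon, 7 serine and glycine and 7 histidine genes. The highest of the other 9 splits gave 0 in each by limma, and at most 143 genes at an unadjusted p under 0.05, in the split by spike level. Each of these 9 splits leaves the strain difference in its spread, which leaves little room for calls, so their counts say little. With strain in the fit, 939 genes lay at an unadjusted p under 0.05 between spike levels, where chance gives about 272, and limma called 0.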
